A study of Bacillus subtilis with 8 samples.

How the data were processed

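Genomic DNA was sequenced from 8 Bacillus subtilis libraries, 2 for each combination of genotype (WT or ΔaddAB, which lacks AddAB) and IPTG (minus or plus). Per the labels' protocols, DNA was extracted with phenol and chloroform and libraries were made with the NEBNext Ultra II DNA kit. Per the submitters' processing notes, fastp and Bowtie2 were used, with no versions given; fastp trims and filters reads and Bowtie2 aligns them. The genome build, mapping filters, treatment of duplicates and strand are not given in the sources used here. Each deposited file holds 1 column with 1 chromosome position per mapped read, unsorted and not normalized, so its lines are read positions and not another unit such as counts per gene or coverage. Because the authors' duplicate handling is unknown, reads copied by PCR may have been counted more than once. Between 2.09% and 7.46% of lines repeated the position of the line before.

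Positions reached 4196641, whereas the last gene of the strain 168 assembly in the gene table used here ends at 4215389. The files therefore use another build, of which no annotation was used here, and no position was matched to a gene. Gene lengths of addA and addB came from that table. Planned tests that needed gene positions or sequence were not run: calls per gene with 14 gene lists of 237 entries, copy number of prophages and mobile elements, correction for GC content, exclusion of rRNA operons and the dif site as terminus. Candidate insertion sites of the reporter were not located for the same reason. The rule for naming genes, which took those with the largest changes past the threshold beside fixed loci, consequently named none; for bins it named up to 5 runs of called bins per direction.

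Reads were counted in windows of 250 bp and summed to 1 kb and 10 kb bins. Each library was divided by its median bin. For tests across the chromosome, log2(scaled coverage + 0.05) of 419 bins of 10 kb was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 8 libraries. Bins with a mean scaled coverage under 0.2 were to be left out, which removed 0 bins. Calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates changes in bins of low coverage. The 6 comparisons were IPTG within each genotype, genotype within each IPTG state, their interaction and genotype over both states.

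Single measures were computed per library with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. They were compared by exact two-sided permutation tests of the difference in means. With 2 libraries against 2 there are 6 arrangements and the smallest p is 0.333. For genotype over both states and for the interaction, labels were permuted within strata, giving 36 arrangements and a smallest p of 0.0556, so no single measure could pass 0.05. The origin-to-terminus ratio was tested on its log2 scale and is the median of 1 kb bins in 100 kb at the origin over that in 100 kb at the terminus. The terminus was the minimum of smoothed WT coverage (101 kb), at 2038 kb. Arm slopes were least-squares fits of log2 bin coverage on distance from the origin, without the addAB locus. The 9 measures were not corrected for their number.

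Groups, tests, measures planned from the labels and their alternatives were fixed before the data were examined. The empty stretch at the addAB locus, the positions of the terminus and of the step at 323 kb, the notch at 1930001 to 1940000, the raised segment at 2140001 to 2270000 and the ratio of right to left arm were chosen afterwards. The step was taken where the mean log2 coverage of all 8 libraries fell most between adjoining 50 kb windows of the right arm, since the planned loci were not located. The notch was found by the contrast of genotypes, and the segment was bounded by bins called between genotypes with IPTG after subtraction of each library's gradient. Notch values are medians of 1 kb bins against flanks of 20 kb starting 30 kb away, and segment values use flanks of 50 kb. The search for the empty stretch bridged single windows outside its limits. Errors of the left-arm tests are jackknife errors over 10 blocks of adjoining 20 kb bins. Waves of coverage were taken as the difference between WT plus and WT minus IPTG replicate 1, smoothed trends removed, and each library's share of them was fitted outside the regions tested. Libraries keep their labels throughout.

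The bin test was tested on simulated data for genotype over both IPTG states, with 60 of 419 bins changed. It called 8 of 20 bins changed by 0.1 (log2), 20 of 20 changed by 0.2, 20 of 20 changed by 0.4 and 4 of 359 unchanged bins. The simulation added a spread of 0.05 (log2) to counting noise, less than the real libraries showed, so it does not give the power for them. Simulated steps of -0.5 returned as -0.55 to -0.50, notches of -0.7 as -0.76 to -0.64 and segments of 0.3 as 0.27 to 0.32. The simulated step was measured with the left-arm slope subtracted, whereas reported steps subtract the right-arm slope, which includes the step. The simulated segment had other bounds than the reported one. The step and the segment were therefore not checked exactly as reported.

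Depth ranged from 726525 to 7623970 reads, 10.5-fold, giving counting errors of 0.742% to 2.40% per 10 kb bin. No pair of libraries differed by less than sampling noise. The closest pair, replicate 2 of both ΔaddAB groups, differed by 0.049 (root mean square log2 over 20 kb bins), where counting error alone gives 0.025. Alternatives covered bin size, scaling, pseudocount, low-coverage filter, weights, moderation, fits on 4 libraries, a replicate block, windows, flanks, slope estimators, counting repeated positions once and leaving out each library.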

Results

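The measurement was whole-genome sequencing of genomic DNA from Bacillus subtilis grown in LB medium to an optical density of 0.5. Every strain carried the luxABCDE operon, a set of bioluminescence genes used as a reporter, in the head-on orientation, so that its transcription runs against the replication fork. The operon was left uninduced or was induced with IPTG, a lactose analogue that relieves repression by the lac repressor. The strains were wild type (WT) or lacked AddAB (ΔaddAB), a helicase-nuclease that processes double-stranded DNA ends for recombinational repair. The 4 groups held 2 libraries each, 8 libraries in all. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

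The files listed 7623970 and 5060098 mapped reads for WT minus IPTG replicates 1 and 2, and 726525 and 2173576 for WT plus IPTG. They listed 1956645 and 1473637 reads for ΔaddAB minus IPTG, and 3061915 and 4539368 for ΔaddAB plus IPTG. A 10 kb bin of average coverage therefore carried a counting error between 0.742% in the deepest library and 2.40% in the shallowest, WT plus IPTG replicate 1. Reads copied by PCR are not independent molecules, so such errors and the limits given for counts of 0 cover counting error only. Positions are those of the files, on a chromosome whose build is not given in the sources used here, and position 1 was taken as the replication origin.

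The addAB locus was examined first, because it checks the genotype labels. Stretches of 1 kb or more that were empty in some libraries and covered in all others were searched for without use of the labels, in all 254 choices of 1 to 7 of the 8 libraries. Windows of 250 bp counted as empty under 0.05 of the library mean and as covered over 0.25. With these limits 1 stretch was found, from 1128001 to 1135250, a length of 7250 bp, and it was empty in this sense in the 4 libraries labelled ΔaddAB. Limits of 0.02 to 0.2 for empty and of 0.25 or 0.5 for covered, added after the data were seen, likewise gave 1 stretch of 7250 bp each. For comparison, addB and addA are neighbouring genes of 3501 and 3699 bp in the reference assembly of the species whose gene table was used. Reads within the stretch numbered 10600, 6937, 1177 and 3156 in the WT libraries. They numbered 15 and 1 in ΔaddAB minus IPTG, where the flanking 20 kb predicted 2817 and 1001, and 0 and 1 in ΔaddAB plus IPTG, where 4498 and 3182 were predicted. The count of 0 allows up to 0.0667% of the predicted reads. Median coverage of the stretch was 93.0% ± 9.77 of the library median in WT (SD, n = 4) and 0% in all 4 ΔaddAB libraries, with no test, because the stretch is defined by this difference. The libraries that the search parted from the others were thus those of 1 genotype label, whereas DNA reads hold no such check of the IPTG labels.

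**Figure D1:**
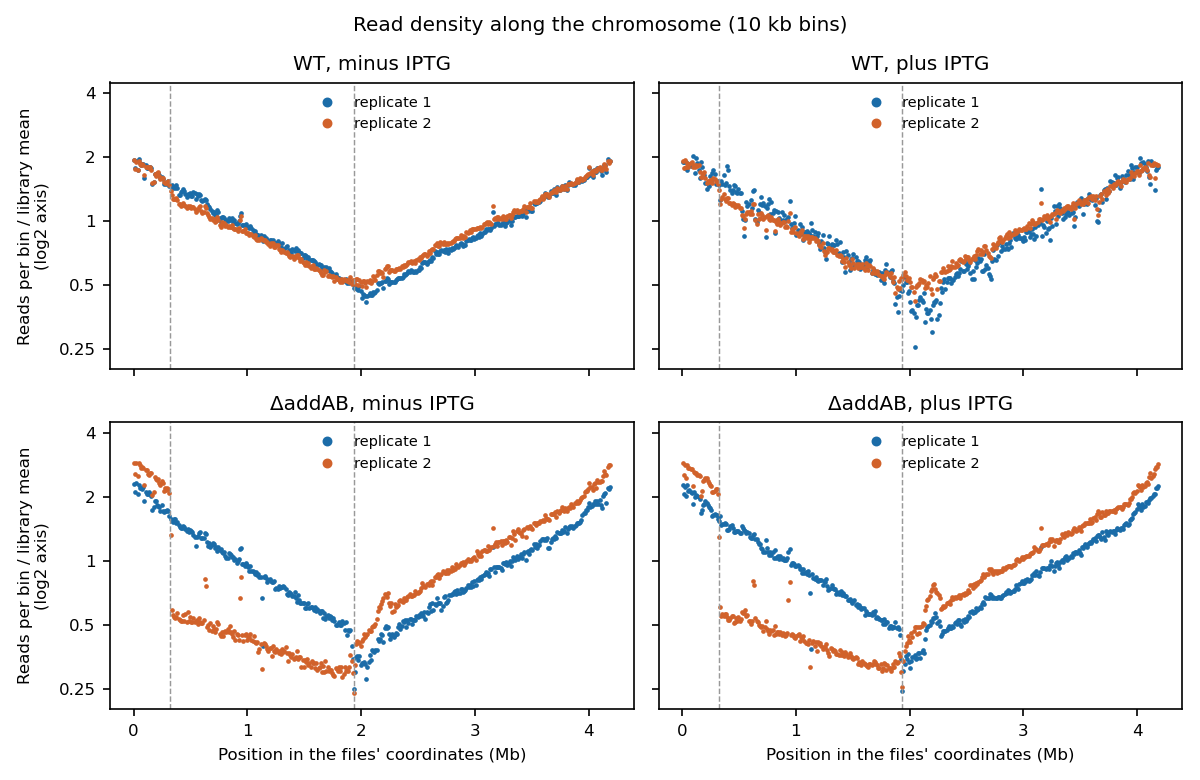
Read density in 10 kb bins, divided by the mean of each library and drawn on a log2 axis against position in Mb, with points coloured by replicate number and 1 panel per group; dashed lines mark 323 kb and 1935 kb. Density near the terminus at 2.04 Mb lay below that at the origin, which is at both ends of the axis, in all 8 libraries, while replicate 2 of both ΔaddAB groups dropped abruptly at 323 kb and had a lower median between 0.4 and 1.8 Mb than at the terminus.

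The comparison of genotypes asks how loss of AddAB altered the distribution of DNA along the chromosome. In growing bacteria, DNA near the origin outnumbers DNA near the terminus because it is copied first, and the ratio of both rises with the number of replication rounds under way. The ΔaddAB libraries had a steeper distribution: their origin-to-terminus ratio was 6.39 ± 0.323 (SD, n = 4), against 4.18 ± 0.529 in WT (SD, n = 4). All 4 ΔaddAB libraries, at 6.83, 6.34, 6.35 and 6.05, lay above all 4 WT libraries, at 4.30, 3.72, 4.88 and 3.82.

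The mean difference in the log2 ratio was 0.62, against a pooled spread within groups of 0.15 (exact two-sided permutation test within IPTG states, p = 0.0556, the smallest possible). Without IPTG the ratio was 6.58 ± 0.348 in ΔaddAB and 4.01 ± 0.412 in WT (SD, n = 2 each), and with IPTG it was 6.20 ± 0.213 and 4.35 ± 0.748. Comparisons of 2 libraries with 2 cannot give a p below 0.333, and both stood at that value (exact permutation). The difference over both states moved to 0.93 with the terminus at 1935 kb, a position chosen after the data were seen, and to 0.42 when the ratio was taken from fits of both arms, where the difference with IPTG was 0.33 in place of 0.52.

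The left arm of the chromosome, which is read from the end of the coordinates towards the terminus, declined in both genotypes. Its slope was -1.05 ± 0.04 log2 units per Mb in ΔaddAB and -0.94 ± 0.10 in WT (SD, n = 4 each; exact permutation p = 0.167), and without IPTG it was -1.07 ± 0.05 and -0.90 ± 0.07, with no overlap (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). With IPTG it was -1.03 ± 0.04 and -0.98 ± 0.13, with overlap (SD, n = 2 each; exact permutation p = 1), a difference of -0.05 that was 0.043 without WT plus IPTG replicate 2. On the right arm the slopes were -1.26 ± 0.06 and -0.96 ± 0.04, with no overlap between genotypes (exact permutation p = 0.0556). That right-arm difference of -0.30 was 0.05 in a fit starting 0.4 Mb from the origin and 0.03 in a rank-based Theil-Sen fit, but these averages hold opposite signs. From 0.4 Mb on, the slopes labelled replicate 1 were -1.20 in both ΔaddAB groups, against -0.96 and -1.004 in WT without and with IPTG, and those labelled replicate 2 were -0.53 and -0.50, against -0.83 in both WT groups.

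A second feature of the ΔaddAB libraries lay in the terminus region, where replication forks from both arms meet. In the 10 kb from 1930001 to 1940000, coverage in the ΔaddAB libraries was 61.7%, 66.8%, 59.6% and 67.3% of that in flanks on both sides. In the WT libraries it was 95.7%, 99.6%, 109% and 106% of the flanks. The reference was the mean of both flanks on the log2 scale, and in ΔaddAB the flanks differed in level. Relative to the library mean, the ΔaddAB notch lay at 0.25, 0.24, 0.25 and 0.25. The flank before it lay at 0.46, 0.31, 0.49 and 0.33, and the flank past it at 0.35, 0.42, 0.35 and 0.43. The notch was thus below both flanks in each ΔaddAB library, but by less against the lower flank. As log2 values, this notch measured -0.65 ± 0.09 in ΔaddAB and 0.04 ± 0.09 in WT (SD, n = 4 each), a difference of -0.69 (exact two-sided permutation p = 0.0556, the smallest possible). The notch was of similar depth with and without IPTG in ΔaddAB, at -0.66 ± 0.12 and -0.64 ± 0.08 (SD, n = 2 each). Its position was chosen from the genotype contrast itself, so the p-value is not independent evidence for it. A notch as deep, -0.74, lay elsewhere in the terminus region of WT plus IPTG replicate 1, at 2040001 to 2050000. In the libraries labelled ΔaddAB minus IPTG replicate 2 and ΔaddAB plus IPTG replicate 2 the lowest notch values lay just past the step, at -0.99 each. The flanks used there lie on opposite sides of the step, so these values reflect the step and not a local dip.

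Farther along, the 130 kb from 2140001 to 2270000 were raised against their flanks in the ΔaddAB libraries, by 0.27 ± 0.09 (log2; SD, n = 4), against -0.05 ± 0.16 in WT (SD, n = 4). Values were 0.14 and 0.25 in ΔaddAB minus IPTG, 0.32 and 0.35 in ΔaddAB plus IPTG, 0.08 and 0.06 in WT minus IPTG, and -0.25 and -0.09 in WT plus IPTG. The difference of 0.32 had an exact permutation p of 0.0556, the smallest possible, and the bounds of the segment were likewise chosen on these libraries. It was 0.13 without IPTG and 0.51 with IPTG, the contrast that set the bounds. With waves of coverage subtracted, the difference over both states was 0.21.

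**Figure D2:**
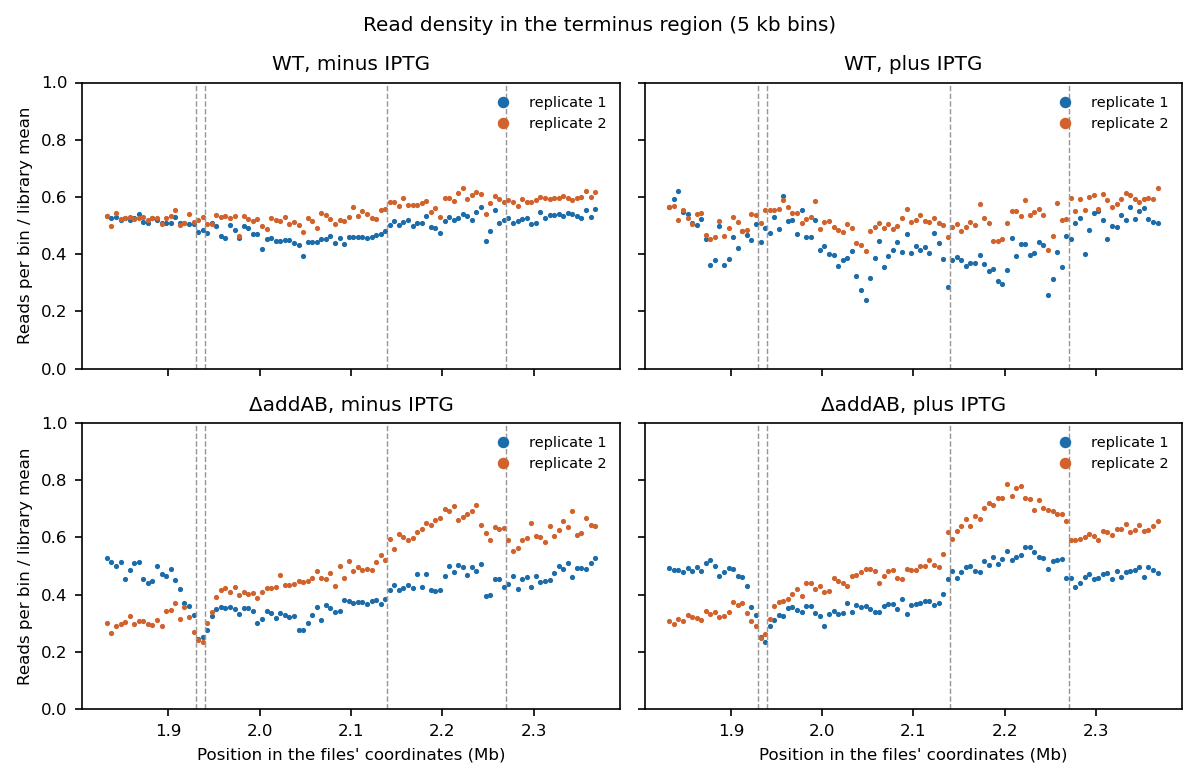
Read density in 5 kb bins around the terminus, divided by the mean of each library, against position in Mb, with 1 panel per group and points coloured by replicate number; dashed lines bound the notch and the raised segment. Density dips between 1930001 and 1940000 in the 4 ΔaddAB libraries, to between 59.6% and 67.3% of the mean of both flanks, and in none of the 4 WT libraries.

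Tested bin by bin without a replicate block, 1 bin passed the threshold between genotypes, the bin from 1130001 to 1140000 that holds most of the empty stretch. Over both IPTG states its log2 difference was -1.36 ± 0.25 (SE; limma, Benjamini-Hochberg adjusted p = 2.27e-05), and it was lower in 4 of 4 ΔaddAB libraries than in any WT library. Among the 419 bins of 10 kb, 37 had an unadjusted p under 0.05 over both states. With IPTG the same bin was called, at -1.44 ± 0.35 (SE; limma adjusted p = 0.0196), among 9 bins with an unadjusted p under 0.05, and without IPTG limma called 0 bins, with 2 at an unadjusted p under 0.05. The call with IPTG was lost when any 1 of the WT libraries or ΔaddAB plus IPTG replicate 2 was left out. The count over both states rose to 58 when ΔaddAB minus IPTG replicate 1 was left out, 47 of them higher in ΔaddAB, and to 39 without ΔaddAB plus IPTG replicate 1, 34 of them higher. Scaling each library to its origin in place of its median bin gave 197 bins, all lower in ΔaddAB. With the replicate number as a block, limma called 37 bins over both states, 34 of them higher in ΔaddAB, and 1 without IPTG. The labels do not state that replicates of the same number are paired.

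The comparison of induced with uninduced WT cells asks what head-on transcription of the operon did to the replication profile when AddAB was present. No bin of the chromosome was called (limma, 0 of 419 bins, and 0 at an unadjusted p under 0.05). The shared fit takes its spread from every group. Replicates minus and plus IPTG differed by 0.11 and 0.16 in WT but by 0.73 and 0.71 in ΔaddAB (root mean square log2, 20 kb bins). A count of 0 therefore does not show that IPTG had no effect, here or in the comparisons below. Unadjusted p-values under 0.05 were found in 72 bins once each library's gradient was subtracted and in 23 bins in a fit of the 4 WT libraries alone, with 0 bins called in either. The origin-to-terminus ratio was 4.35 ± 0.748 with IPTG and 4.01 ± 0.412 without (SD, n = 2 each; exact permutation p = 0.667). Of the alternatives run, weighting libraries by their quality made calls, of 11 bins that were all lower with IPTG, and no other did.

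Coverage fell abruptly on the right arm near 323 kb, but unequally between the replicates of each group. The step was defined as log2 coverage of the 50 kb on the terminus side minus that of the 50 kb on the origin side, with the arm slope subtracted. It measured -0.02 and -0.17 in WT minus IPTG replicates 1 and 2, and 0.02 and -0.22 in WT plus IPTG. The mean effect of IPTG in WT was -0.004 against a pooled spread of 0.14 (exact permutation p = 1). In the libraries labelled WT minus IPTG replicate 2 and WT plus IPTG replicate 2, the fall exceeded those at all 68 other places examined. These lay 50 kb apart outside the terminus region. In the WT replicates labelled 1, 14 and 34 of them had as large a fall. The step was placed where the mean of all libraries fell most, which favours such a rank.

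The same comparison in ΔaddAB cells asks what induction did without AddAB. Again limma called no bin (0 of 419, and 0 at an unadjusted p under 0.05, or 7 with the gradient subtracted), and the origin-to-terminus ratio was 6.20 ± 0.213 with IPTG and 6.58 ± 0.348 without (SD, n = 2 each; exact permutation p = 0.667). At 323 kb the libraries labelled ΔaddAB minus IPTG replicate 2 and ΔaddAB plus IPTG replicate 2 had steps of -1.88 and -1.84, so that coverage past the step was 27.1% and 28.0% of that before it once the slope was removed. The libraries labelled replicate 1 had steps of -0.07 and -0.06, and 3 and 2 of the 68 other places had as large a fall in them. The group means of -0.98 ± 1.28 without IPTG and -0.95 ± 1.25 with IPTG (SD, n = 2 each) differed by 0.02, far less than the spread within groups (exact permutation p = 0.667).

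**Figure D3:**
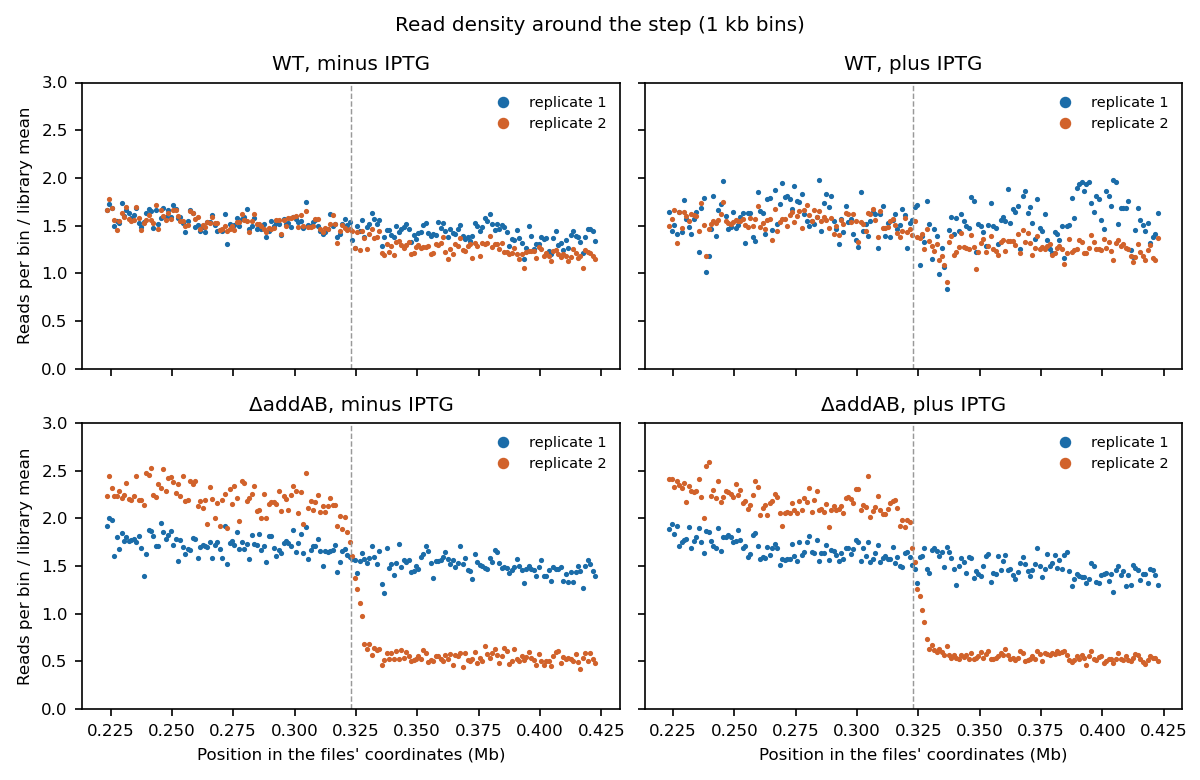
Read density in 1 kb bins within 100 kb of 323 kb (dashed line), divided by the mean of each library, against position in Mb, with 1 panel per group and points coloured by replicate number. Density falls between 318 and 329 kb in replicate 2 of ΔaddAB minus IPTG and of ΔaddAB plus IPTG, with steps of -1.88 and -1.84 on the log2 scale.

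The lower coverage reached from the step to the region of the notch and ended short of the terminus at 2038 kb. In the flank before the notch, the ΔaddAB replicates labelled 2 had 0.31 and 0.33 times their library mean (minus and plus IPTG), against 0.46 and 0.49 in those labelled 1. In the flank past the notch they had 0.42 and 0.43, against 0.35 in both labelled 1. Between 0.4 and 1.8 Mb from the origin, the right arm held 36.2% and 37.7% of the coverage of the left arm in the libraries labelled ΔaddAB minus IPTG replicate 2 and ΔaddAB plus IPTG replicate 2. It held 99.3% and 103% in the libraries labelled replicate 1. In WT the right arm held 96.4% and 85.4% without IPTG, and 97.4% and 85.6% with IPTG. The fall itself took 10 kb in the library labelled ΔaddAB minus IPTG replicate 2 and 11 kb in ΔaddAB plus IPTG replicate 2, starting at 318 kb in both. The site of the operon is not given in the sources used here, and 0 windows of 250 bp lay under 0.05 of the mean in all 8 libraries, while read positions cannot show an insertion, so whether it lies at the step is left open.

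The planned measure of DNA loss at the terminus, coverage within 50 kb of 2038 kb minus the value extrapolated from both arms, did not separate the groups. It was 0.09 ± 0.37 in ΔaddAB and -0.05 ± 0.13 in WT (log2; SD, n = 4 each; exact permutation p = 0.5). In ΔaddAB replicates 1 and 2 it was -0.26 and 0.40 without IPTG, and -0.18 and 0.41 with IPTG. The arm fits of the replicates labelled 2 include the step, and with arms from 0.4 Mb on their values were 0.15 and 0.16 and the genotype difference was 0.020 in place of 0.14.

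The interaction asks whether induction acted differently with and without AddAB. For the step it was 0.03 (log2; exact permutation p = 0.722), for the origin-to-terminus ratio -0.19 (p = 0.389, exact permutation) and for the notch -0.16 (p = 0.222, exact permutation), or -0.022 with flanks starting 60 kb away (p = 0.778, exact permutation). Limma called 0 bins, with 0 at an unadjusted p under 0.05, and again 0 with the gradient subtracted, where 74 had an unadjusted p under 0.05. In the raised segment IPTG went with -0.24 in WT and 0.14 in ΔaddAB, a difference of 0.38. No test of it is given, because the bounds of the segment were chosen on the contrast of genotypes with IPTG, which favours such a difference, and it was 0.087 once waves of coverage like those of WT plus IPTG replicate 1 were subtracted.

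**Figure D4:**
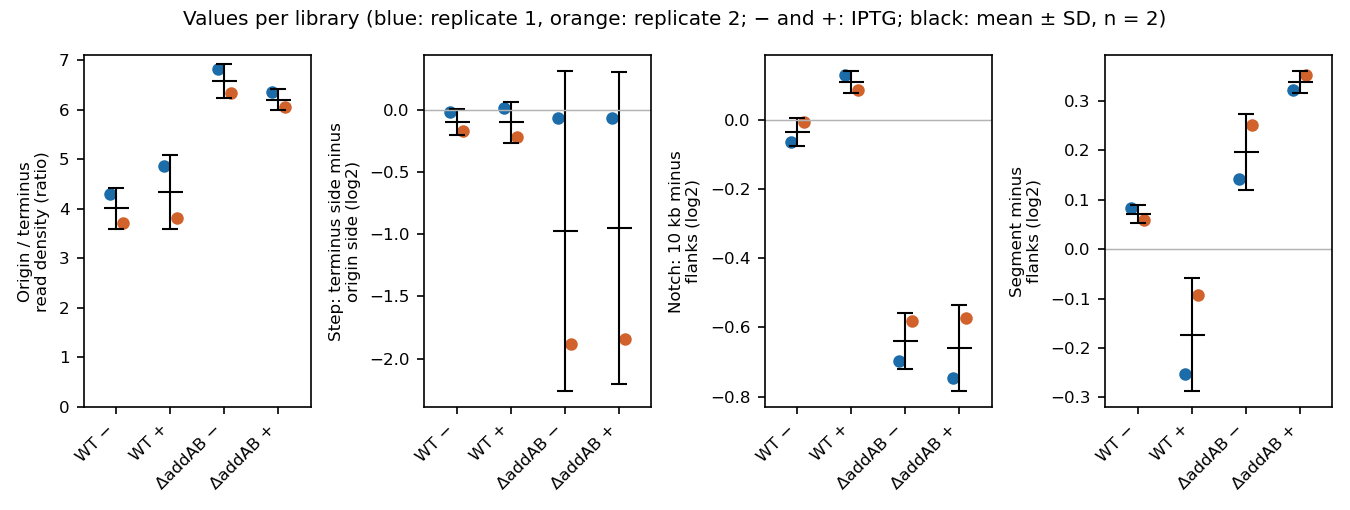
Values per library for the origin-to-terminus ratio, the step at 323 kb, the notch and the raised segment (the last 3 in log2 units), by group, with blue and orange points for replicates 1 and 2 and black bars for mean ± SD (n = 2). The ratio and the notch separate ΔaddAB from WT in all 8 libraries, whereas the step separates replicates within the ΔaddAB groups.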

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

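The tests of exchanged labels on the left arm, of waves in the IPTG effects on the segment, of replicate sets, of induction as labelled, of the notch as a consequence of the step and of other splits of the libraries were chosen after the results were seen, as were the positions of the empty stretch, the step, the notch and the segment.

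Within the empty stretch that marks the addAB locus, the library labelled WT plus IPTG replicate 1 had a median coverage of 107.7% of its library median, apart from the other 3 WT libraries. It is the shallowest library, and 1 of 17 groups examined in this way stood out, where chance marks about 1 in 20.

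In the raised segment from 2140001 to 2270000, IPTG went with lower coverage in both WT plus IPTG libraries (-0.25 and -0.09, against 0.08 and 0.06) and with higher coverage in both ΔaddAB plus IPTG libraries (0.32 and 0.35, against 0.14 and 0.25). The difference between the effects was 0.38. It has no independent test, because the segment was bounded by the contrast of genotypes with IPTG, which selects for such a difference.

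A fall in coverage at 323 kb that exceeded those at all other places examined occurred in 1 library of every group. Induction as labelled is argued against as its cause, because 4 of the 8 libraries went against their label. Those were replicates 2 of the minus IPTG groups, with the fall, and replicates 1 of the plus IPTG groups, without it. Counting noise from unequal depth is argued against too, because the lowest step after thinning all libraries to equal reads was -1.86. Random thinning keeps relative coverage, so a bias that goes with the depth of a library was not tested. An exchange of IPTG labels within each genotype and separate sets of cultures or libraries behind the replicate numbers cannot be told apart. The left arm is not reached by the fall. There, 3 of the 8 libraries lay closer to the same number in the other IPTG group than to their group partner. Differences between replicates correlated there between WT and ΔaddAB groups at 0.036 to 0.61 with linear trends removed. With the trends kept they correlated at 0.68 to 0.83. The left-arm slope was steeper in replicate 1 than in replicate 2 of every group, so the trends removed themselves went with replicate number. Bounds for excluding these explanations, 4 or fewer libraries and a lowest correlation under 0.1, were set after the fall was seen but before these values. The 3 libraries and the correlation of 0.036 met them. Neither did so by more than its spread, which was added after they were seen. With a jackknife error allowed, 5 libraries lay closer, and the error of the correlation was 0.14. An exchange would show on the left arm only if induction altered that arm, which is not known, so the first test cannot exclude an exchange. The segment values given above followed the IPTG labels, in opposite directions in the genotypes. The left-arm slope next to the origin did so too, but in ΔaddAB only narrowly. It was -1.42 and -1.799 per Mb in ΔaddAB minus IPTG, and -1.822 and -1.954 in ΔaddAB plus IPTG. Its excess over the slope farther out overlapped there, at -0.42 and -0.86 without IPTG and -0.78 and -0.997 with IPTG. These measures were chosen after the data were seen and decide nothing. Which libraries were induced therefore stays open, and effects of IPTG given for the labelled groups rest on the labels alone.

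The notch from 1930001 to 1940000 was present in all 4 ΔaddAB libraries. Counting noise from unequal depth is argued against, because after thinning to equal reads the shallowest notch of the ΔaddAB libraries was still -0.58. Thinning keeps relative coverage, so a bias that goes with depth was not tested. The genotype difference with waves of coverage like those of the shallowest WT library subtracted was -0.62, with a pooled spread of 0.09. These waves were a rise at the notch, at 0.13 in WT plus IPTG replicate 1 against -0.06 in WT minus IPTG replicate 1. Subtracting them could hardly remove a dip, so the value argues only against waves of that same shape. Waves with a dip at this place were not tested. The step is argued against as its source, because the ΔaddAB library with the smallest fall at 323 kb had a notch of -0.75. Less DNA there in cells without AddAB may be a biological difference, as a hypothesis found on these same libraries, but its size alone does not set it apart, since WT plus IPTG replicate 1 had a notch of -0.74 at 2040001 to 2050000, and a sequence difference between strains and GC content were not tested.

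For the raised segment in the ΔaddAB libraries, counting noise from unequal depth is argued against, because the genotype difference after thinning was 0.34. Here too a bias that goes with depth was not tested. The genotype difference moved from 0.32 to 0.21 when waves like those of the shallowest WT library were subtracted, where the waves alone needed a value under 0.1. The pooled spread was 0.07 before subtraction (0.027 after it, too small because subtraction makes a pair of WT libraries equal), so the value clears the other bound set beforehand, 0.2, by less than its spread, and how to read this was settled after it was seen. These waves were a dip at the segment, at -0.25 in WT plus IPTG replicate 1 against 0.08 in WT minus IPTG replicate 1. Subtracting a dip could hardly lower the raised values of ΔaddAB, so the test cannot exclude waves as the source. Waves with a rise at this place were not tested. For the opposite IPTG effects, whose difference moved from 0.38 to 0.087, waves and induction cannot be told apart, since the waves were taken from a library that is itself compared. An effect of the genotype stays open as a hypothesis, with GC content, copy number of prophages and mobile elements, and sequence differences between strains not tested.

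For the count of bins called between genotypes over both IPTG states, 8 of the 35 splits of the libraries into 4 and 4, the real one included, gave at least the real count of 1, so a count of 1 does not by itself exclude chance. The bin called is the one at the addAB locus, where coverage was 0% of the library median in 4 of 4 ΔaddAB libraries and 87.6% to 107.7% in WT. The highest other split called 43 bins. It set the replicates labelled 1 against those labelled 2, which points to a structure of the libraries that follows replicate number.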

How the results depend on the processing

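Among the tests below, those with the terminus opposite the origin or at the notch, arms from 0.4 Mb, flanks of the addAB locus, repeated positions counted once and all tests of the notch, the segment and the arm ratio were chosen after the data were seen. Of the alternative values, 551 left the count of called bins equal or similar, or moved a single measure by no more than its pooled spread. Within that spread the sign can change. A further 39 moved by more than the spread, 18 counts of bins were larger and 8 were smaller. For single measures the permutation tests had no way to reach 0.05, so these say nothing on stability beyond size. In all alternatives run, the notch stayed lower and the origin-to-terminus ratio higher in ΔaddAB over both IPTG states. Where no construction is named, the cause was not tested.

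Bin calls for IPTG in ΔaddAB and for the interaction stayed at 0 throughout, and those for IPTG in WT rose to 11, all lower, with array weights. For genotype without IPTG, with IPTG and over both states, scaling to the origin gave 184, 166 and 197 bins; 2 of the 166 were higher and all others lower, since the origin is then equal by construction. Trended robust moderation gave 2 in each. With 5 kb bins, 1 was called without IPTG and 2 over both states. With IPTG, 20 kb bins, scaling to mean coverage and a pseudocount of 0.2 each gave 0, and subtracting the gradient gave 33, of which 25 were higher. Scaling to mean coverage gave 2 over both states. Leaving out single libraries gave 0 to 1 without IPTG, 0 to 1 with IPTG and 1 to 58 over both states, with 58 (47 higher) without ΔaddAB minus IPTG replicate 1 and 39 (34 higher) without ΔaddAB plus IPTG replicate 1; a group left with 1 library is assumed to vary like the others.

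The labels share only replicate numbers, not a stated pairing. With the replicate number as a block, limma called 1 bin without IPTG and 37 over both states, 34 of them higher and 3 lower, the bin of the notch among them (-0.73, limma adjusted p = 0.00873); no other count of calls changed. Differences between replicates 1 and 2 correlated at 0.61 to 0.997 between groups over bins, which are not independent.

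The genotype difference in the log2 origin-to-terminus ratio without IPTG, with IPTG and over both states was 0.51, 0.33 and 0.42 from arm fits, and 0.93, 0.94 and 0.93 with the terminus at the notch, which lies in the DNA that is low in ΔaddAB. At the notch the interaction in that ratio was 0.011 and IPTG in ΔaddAB -0.0093; opposite the origin the latter was -0.019. The right-arm slope difference, in the same order, was 0.0045, 0.063 and 0.033 by Theil-Sen and 0.030, 0.062 and 0.046 from 0.4 Mb on, a range that leaves out the step. The terminus measure for genotype with IPTG was -0.15 at the notch. Coverage of the addAB locus for genotype without IPTG differed by -87.5 points with means, -95.3 against flanks and -88.7 with repeats counted once, and for IPTG in ΔaddAB by -0.268 with means and -0.298 against flanks. Leaving out single libraries moved it without IPTG from -88.6 to -87.6.

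Interactions, and the effects within 1 genotype or IPTG state behind them, moved when 1 library was left out. The interactions ranged from -0.37 to -0.017 for the origin-to-terminus ratio, 0.027 to 0.21 for the left-arm slope, -0.18 to 0.49 for the terminus measure, -0.88 to 0.94 for the step, -0.25 to -0.077 for the notch and -19.6 to -0.107 points for the addAB locus. The effect of IPTG on the step in ΔaddAB ranged from -0.88 to 0.93, so its sign rests on which library is kept. GC correction, alone or with the block, rRNA operons kept in, all alternatives for calls per gene and those for prophages were not run, for want of an annotation of the build. Depth limits WT plus IPTG replicate 1 most, at a counting error of 2.40% per 10 kb bin.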

Other observations

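The measures in this part were chosen after the data were seen.

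Next to the origin, the left arm was steeper in the ΔaddAB libraries than farther out. Over the 0.25 Mb nearest the origin, log2 coverage changed by -1.42 to -1.95 per Mb in the 4 ΔaddAB libraries, and between 0.4 and 1.4 Mb by -0.94 to -1.04. In WT minus IPTG the slopes near the origin were -1.03 and -0.97, against -0.98 and -0.83 farther out. In WT plus IPTG they were 0.12 and -0.50, against -0.90 and -0.76. The excess near the origin was -0.77 ± 0.25 per Mb in ΔaddAB and 0.27 ± 0.53 in WT (SD, n = 4 each; exact two-sided permutation p = 0.0556, the smallest possible). The WT mean rests on WT plus IPTG replicate 1, the shallowest library, at 1.03, and was 0.0205 without it. The genotype difference was -0.54 without IPTG and -1.53 with IPTG.

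A pair of narrow loci on the right arm did not share the low coverage past the step. They were found by a search for bins far above their local median in a pair of libraries or more. Their height above the surroundings is thus partly a result of how they were selected. At 628001 to 632000, coverage was 1.79 and 1.74 times the library mean in the libraries labelled ΔaddAB minus IPTG replicate 2 and ΔaddAB plus IPTG replicate 2, which was 3.52 and 3.38 times their surroundings. At 938001 to 943000 it was 1.61 and 1.57 times the mean, or 3.66 and 3.49 times the surroundings. In the other 6 libraries both loci lay between 1.34 and 2.05 times the library mean, and between 1.14 and 1.802 times their surroundings. Which genes lie there was not analysed here. Mapping filters are not known and rRNA operons were not excluded, so these values do not show that DNA there escaped the fall.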
